A study of Mus musculus with 9 samples.

How the data were processed

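Organoids from mouse ileum and colon crypts were profiled in 9 libraries, 3 for each of wild type ileum, wild type colon and Satb2-deficient colon. Per the labels' protocols the libraries were made with a non-directional kit for messenger RNA, so the reads do not mark strand. The authors deposited raw counts per gene symbol, made with featureCounts in its default unstranded mode per the labels' series design text. Trim Galore, STAR, featureCounts, DESeq2 and the build GRCm38 are listed in the submitters' processing notes, with no version or role. The authors also deposited a normalized signal for 14442 of the 54735 genes, and each value in it was found to equal the raw count divided by 1 factor per library. Groups and replicate numbers were taken from the sample titles.

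Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr by group, a quasi-likelihood fit over all 9 libraries with 1 mean per group, and Benjamini-Hochberg adjustment over the 13456 genes tested, with a threshold of 0.05. These genes hold 99.9% or more of the counts in each library. The common biological coefficient of variation was 0.0813. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic and are approximate. CPM values use the TMM factors. Replicates were compared by a chi-square test of their counts over genes, and no pair agreed within sampling noise. A group with no count is given a floor of 3 counts over its 3 libraries together, between 0.0509 and 0.0537 CPM, and folds against it are lower bounds. Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

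Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over lists within a comparison, and again with a correlation estimated for each list. The 27 lists cover bile acid handling, fat absorption, brush border enzymes, nutrient transporters, colonic ion and water transport, other colonic markers, secretory and stem cell types, proliferation, transcription factors, fetal genes, antimicrobial, interferon, MHC class II, metabolic, stress and immediate early genes, other cell types and sex-linked genes. The lists, the rule for named genes and the alternatives listed below as fixed beforehand were set before the data were examined. The rule for named genes took Satb2, the 15 highest and 15 lowest log2 fold changes of each comparison among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups compared, leaving out gene models named only by a number or clone, and any list member. Genes named outside this rule are said to be so. Region genes are those called in wild type ileum against wild type colon with a log2 fold change of at least 1. The covariance that shared wild type colon libraries add, and the shares in an unchanged knockout, were found by 20 simulations of such a knockout from the fitted means and dispersions. Covariance and variance stand here for mean products and mean squares over genes, with no mean taken off. The fraction of the distance is thus the slope of a line through the origin. Gene positions come from GENCODE M21 on GRCm38, matched by symbol.

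The scripts were tested on simulated data for Satb2-deficient against wild type colon, with 200 of 13103 genes changed. The real comparison called 7486 of 13456 genes, so the call rates given next are for a setting with far fewer changes. Of genes changed 1.5-fold 65.7% were called in the right direction, of those changed 2-fold 77.6% and of those changed 4-fold 95.5%. Unchanged genes made up 9.14% of the calls, above the 5% aimed at. A knockout placed at 0.8 of the distance to ileum was found at 0.798, with no noise covariance or variance taken off. The reported fraction has both taken off, and that step was not tested. A list raised 1.5-fold was called, and 0 of 20 unchanged lists were. Genes were simulated independently of each other, while the estimated correlation in the real interferon list was 0.567. The simulation therefore does not show how often the preset correlation calls unchanged lists of correlated genes.

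Alternatives fixed beforehand were RLE and upper quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2(value + 1) of the deposited normalized signal, fits of the compared groups alone, the replicate number as a block, a log2 fold change of at least 1 beside the adjusted p, region genes with no minimum fold or a log2 fold change of at least 2, the 20 genes with most counts and mitochondrial genes left out, and each library left out in turn. Lists were also tested with fry and on log2(value + 1) of the normalized signal. Leaving out X and Y genes, an offset for GC content and length, and a prior count of 2 for the fraction were added after the data were examined.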

Results

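Gene expression was measured by bulk RNA sequencing in organoids, which are epithelial cultures grown in 3 dimensions from intestinal crypts. The crypts came from mice in which the chromatin regulator Satb2 can be deleted in the intestinal epithelium by tamoxifen, or from control mice, 30 days after the injection. There were 3 groups of 3 libraries each: wild type colon, wild type ileum and Satb2-deficient colon. All cultures were kept in a medium made for large intestine, passaged a single time and differentiated before RNA was taken. The libraries held between 17299204 and 20831356 counted reads. The labels do not say whether replicates were separate animals or separate cultures, so the p-values measure the spread between these libraries, which may be technical in part.

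Within each group, log2 CPM (counts per 1e+06 reads, TMM-normalised) correlated between libraries at 0.989 to 0.993 across genes, which are not independent replicates. Satb2-deficient colon correlated with wild type ileum at 0.966 to 0.971 and with wild type colon at 0.909 to 0.915. Wild type ileum and wild type colon correlated at 0.889 to 0.896. The groups also differed in sex-linked transcripts. Xist, transcribed from the inactive X chromosome, was at 113 ± 16.9 CPM in Satb2-deficient colon and 121 ± 7.26 CPM in wild type ileum (SD, n = 3) and had no count in wild type colon. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 27.2 to 60.1 CPM in wild type colon and no count in the other 6 libraries. Every comparison with wild type colon therefore coincides with a difference in these transcripts, which Satb2-deficient colon and wild type ileum do not show between them. Mitochondrially encoded genes took 0.717% ± 0.134 of the reads in Satb2-deficient colon, 1.43% ± 0.167 in wild type colon and 1.12% ± 0.148 in wild type ileum (SD, n = 3). Markers of other cell types were scarce. Of 14 mesenchymal and 16 blood, endothelial and glial markers, 2 in each list had enough counts to be tested, and of these 4 the mesenchymal receptor Pdgfrb had the most counts, with 7.74 ± 0.349 CPM in Satb2-deficient colon, 2.86 ± 0.586 in wild type colon and 10.5 ± 0.966 in wild type ileum (SD, n = 3).

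**Figure D1:**
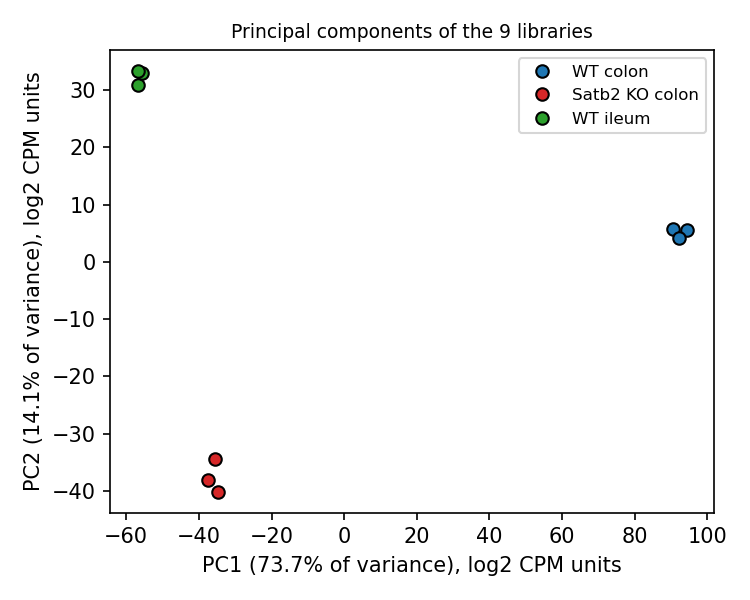
Each point is 1 of the 9 libraries on the first principal components of log2 CPM, with the share of variance on each axis label. The horizontal axis (73.7% of variance) separates wild type colon from the other groups, and the vertical axis (14.1%) separates Satb2-deficient colon from wild type ileum.

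Satb2 (GRCm38 chromosome 1, 56793981 to 56978650) was the deleted gene and was read first. It stood at 48.1, 48.7 and 55.2 CPM in the libraries of Satb2-deficient colon and at 201, 223 and 217 CPM in those of wild type colon. In wild type ileum it was at 25, 35.6 and 34.9 CPM. The log2 fold change of Satb2-deficient against wild type colon was -2.08 ± 0.10 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.4e-16). Counts per gene do not show which exons the remaining reads came from.

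**Figure D2:**
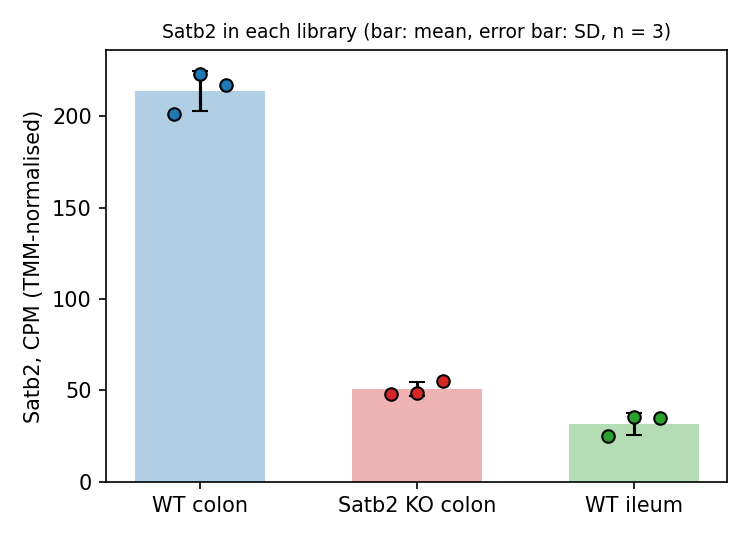
Satb2 in CPM on the vertical axis for each group, with 1 point per library, bars for the mean and error bars for the SD (n = 3). The libraries of Satb2-deficient colon lie between 48.1 and 55.2 CPM, below every library of wild type colon and above every library of wild type ileum.

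The comparison of wild type ileum with wild type colon asked which regional differences organoids keep in a shared large intestine medium. Of 18 genes of fat absorption 16 were higher and 1, Scarb1, lower in ileum (camera adjusted p = 1.2e-13), and all 15 tested genes of Paneth cells, the antimicrobial cells of small intestinal crypts, were higher. The ileal bile acid carriers Slc10a2 (1305 ± 138 against 118 ± 21.8 CPM) and Fabp6 (475 ± 71.6 against 0.0909 ± 0.0682 CPM) were higher in ileum too (mean ± SD, n = 3). The sugar transporter Slc2a2 and the defensins Defa17, Defa22 and Defa30 had no count in wild type colon and were at least 529.8-fold higher in ileum, against a floor of 3 counts over the group. In colon, the carbonic anhydrase Car1 reached 17178 ± 1307 CPM against 262 ± 10.1 in ileum, and the water channel Aqp8 829 ± 108 against 0.169 ± 0.0196. The posterior HOX genes Hoxa9, Hoxa10 and Hoxa13 had no count in ileum and 12.5, 34.3 and 51.2 CPM in colon.

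In all, 3999 genes were higher and 3737 lower in ileum of 13456 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 1680 and 1278 of these differed by a log2 fold change of at least 1. All 15 small intestinal nutrient transporters rose, for example the peptide carrier Slc15a1 by a log2 fold change of 3.86 ± 0.09 (SE), and so did 15 of 16 brush border enzymes and all 15 Paneth genes tested (camera adjusted p = 1.3e-14, 1.3e-14 and 1.2e-13, and 0.0171, 0.0432 and 0.0456 with an estimated correlation). All 10 genes of colonic ion and water transport and 12 of 13 other colonic markers fell, and 1 of the latter rose (camera adjusted p = 2.0e-09 and 2.4e-08). Among 20 proliferation genes 19 were higher in ileum, with Mki67 at 48.3 ± 2.03 against 7.57 ± 2.34 CPM. That list's camera adjusted p was 7.0e-11, and its adjusted p = 0.104 with an estimated correlation. In this comparison 20 of 25 lists passed with the preset correlation and 8 with an estimated one. The counts of members adjusted over the list alone were equal in 23 of the lists. The groups also differ in Xist and Y-linked transcripts.

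The comparison of Satb2-deficient with wild type colon asked what the colonic epithelium expresses once Satb2 is lost. All 15 tested nutrient transporters rose, some from near 0 (camera adjusted p = 5.2e-15). The bile acid carrier Slc10a2 rose from 118 ± 21.8 to 902 ± 9.34 CPM, a log2 fold change of 2.94 ± 0.11 (SE, adjusted p = 8.8e-17, edgeR). The disaccharidase Sis rose from 21.2 ± 2.65 to 6189.9 ± 977 CPM, and apolipoprotein Apoa1 from 7.35 ± 2.04 to 2952 ± 158 CPM. Of 10 genes of colonic ion and water transport 9 fell and 1, Scnn1a, rose (camera adjusted p = 1.7e-08). Car1 fell from 17178 ± 1307 to 170.3 ± 19.6 CPM and Aqp8 from 829 ± 108 to 0.055 ± 0.0561 CPM (mean ± SD, n = 3).

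All 6 tested bile acid genes rose, including Fabp6 (0.0909 to 124 CPM), the basolateral exporter subunit Slc51a and the hormone gene Fgf15. Their camera adjusted p was 1.1e-06, with adjusted p = 0.0521 under an estimated correlation. Of 18 genes of fat absorption and lipoproteins 17 were called higher (camera adjusted p = 3.0e-15), but for Fabp2 and Scarb1 (log2 fold changes 0.18 ± 0.08 and 0.26 ± 0.11, SE, edgeR adjusted p = 0.0461 and 0.0446) the call was lost with RLE factors (adjusted p = 0.0769 and 0.0617). Both calls were also lost without replicate 1 or 2 of Satb2-deficient colon or replicate 1 or 3 of wild type colon (highest adjusted p = 0.194 and 0.189), and Scarb1's without replicate 3 of Satb2-deficient colon (adjusted p = 0.0598). Fabp2 turned to -0.25 (adjusted p = 0.00118) with an offset for GC content and length that was chosen after seeing the data. Mttp, which loads lipid onto apolipoprotein B, rose by a log2 fold change of 6.99 ± 0.12, and Apob itself by 4.36 ± 0.14 (SE). Dgat2 was at 99.5 CPM against 105. All 15 nutrient transporters rose (camera adjusted p = 5.2e-15). Slc2a2 had no count in wild type colon and was at least 864-fold higher, and the sodium and glucose carrier Slc5a1 rose by 2.83 ± 0.08. Among brush border enzymes 12 of 16 rose, with the peptidases Dpp4, Ace2 and Anpep at 235, 627 and 711 CPM against 0.944, 11.9 and 3.47. The other 4, Mgam, Alpi, Mep1a and Xpnpep2, fell, with log2 fold changes of -0.37, -0.26, -1.46 and -1.42. The brush border list had a camera adjusted p of 1.0e-06, with adjusted p = 0.111 under an estimated correlation.

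Of 10 genes of colonic ion and water transport 9 fell (camera adjusted p = 1.7e-08), among them the chloride and bicarbonate exchanger Slc26a3 (-2.73 ± 0.08, SE). The exception was Scnn1a, a subunit of the epithelial sodium channel, which rose from 101 ± 5 to 199 ± 18.7 CPM. Of 13 other colonic markers 12 fell (camera adjusted p = 2.1e-08), including Gsdmc2, Selenbp1 and Ly6g. The exception, 2210407C18Rik, rose from 3.77 ± 0.646 to 47.8 ± 3.09 CPM. The gasdermin C, Ly6, Cyp2c, Cyp3a, Reg3 and defensin genes have near-identical copies, so their single values are uncertain where reads could be split between copies.

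Markers of secretory cells were read list by list. All 15 tested Paneth genes were higher, with lysozyme Lyz1 at 491 ± 33.4 CPM against 0.0547 ± 0.0537 and the protease Mmp7 at 95.5 ± 13.1 against 1.3 ± 0.394 (camera adjusted p = 1.2e-11, and adjusted p = 0.0503 with an estimated correlation). Of 15 goblet cell genes 14 rose (camera adjusted p = 3.7e-10), including the trefoil peptide Tff3, the disulfide isomerase Agr2 and the lineage factors Atoh1 and Spdef. The remaining one, the mucin Muc2, was at 144 ± 44.2 CPM against 104 ± 14. Of 8 genes of colonic deep crypt secretory cells 7 rose (camera adjusted p = 3.7e-05). Reg4 went from 2.28 ± 0.311 to 148 ± 7.59 CPM, and Sycn alone fell. Tff3, Agr2 and Spink4 belong to both of the last lists. Among 18 enteroendocrine genes 13 rose and 2 fell (camera adjusted p = 1.3e-04). Gcg, Sct and Cck rose, while Insl5 and Pyy, hormones of the distal gut, fell, with log2 fold changes of -3.17 and -0.46. All 7 tested tuft cell genes rose (camera adjusted p = 0.00137, and adjusted p = 0.0521 with an estimated correlation), such as Ptgs1 from 0.576 ± 0.187 to 9.05 ± 0.659 CPM.

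Of 20 proliferation genes 17 rose, with Top2a at 29.9 ± 3.66 against 9.01 ± 1.42 CPM (camera adjusted p = 1.1e-06, and adjusted p = 0.173 with an estimated correlation). Stem cell genes went both ways, 4 up and 4 down of 14 (camera adjusted p = 0.922): Smoc2 rose from 1.74 to 31.4 CPM and Prom1 fell from 1772 to 415. Among 15 regional transcription factors of the small intestine 10 rose and 3 fell. Hnf4g rose from 33.8 ± 5.38 to 297 ± 8.92 CPM, Maf from 12.8 ± 0.991 to 108 ± 7.4 and Gata5 from 0.875 ± 0.222 to 15.9 ± 2.91, and Klf4 fell, with a log2 fold change of -1.65. That list's camera adjusted p was 0.00139, and its adjusted p = 0.129 with an estimated correlation. Of 12 caudal and HOX genes 7 fell and 4 rose (camera adjusted p = 0.0188, and adjusted p = 0.144 with an estimated correlation). Hoxa11 and Hoxb13 had no count in Satb2-deficient colon and were at least 67.6-fold and 43.7-fold lower, Hoxa13 was at 0.11 ± 0.0991 against 51.2 ± 4.97 CPM, and Cdx2 fell, with a log2 fold change of -0.96 ± 0.07 (SE). Hoxb6, Hoxb7 and Hoxb9 rose by log2 fold changes of 0.98, 0.67 and 0.55. Counting ignored strand, so reads of a HOX gene, Foxd2 or Xist cannot be told from those of an antisense transcript over it. The counts do not show whether such reads were assigned to the gene or left out.

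Antimicrobial genes mostly rose, 10 of 13 against 3 that fell (camera adjusted p = 2.0e-05). Reg3b went from 1.69 ± 0.322 to 258 ± 22.9 CPM and Pigr from 508 ± 34.3 to 2286 ± 179.5, and Saa1 fell, with a log2 fold change of -3.29. Of 20 genes of xenobiotic metabolism 17 rose and 3 fell (camera adjusted p = 4.9e-10), with Cyp3a11 absent from the counts of wild type colon and at least 734-fold higher. Fatty acid oxidation genes rose in 12 of 18 cases and fell in 4 (camera adjusted p = 0.0187, and adjusted p = 0.321 with an estimated correlation). Heat shock and unfolded protein genes rose in 10 and fell in 3 of 14 cases (camera adjusted p = 9.2e-04, and adjusted p = 0.129 with an estimated correlation), for example the chaperone Hspa5 (1186 ± 113 against 341 ± 27.9 CPM), with Hspa1a among those that fell. Of 16 interferon response genes 13 were lower (camera adjusted p = 0.00139, and adjusted p = 0.348 with an estimated correlation). The wild type colon libraries varied in these genes, with Oasl2 at 65.8 ± 27.9 CPM. Immediate early genes fell in 5 of 9 cases (camera adjusted p = 0.0187, and adjusted p = 0.341 with an estimated correlation). MHC class II, cholesterol synthesis and fetal or regenerative genes did not pass as lists (camera adjusted p = 0.416, 0.173 and 0.945). For the stem cell and the fetal lists the test's direction was down while median and mean were above 0.

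In total 3956 genes were higher and 3530 lower in Satb2-deficient than in wild type colon (edgeR quasi-likelihood, adjusted p under 0.05), of which 1544 and 929 differed by a log2 fold change of at least 1. Of 25 lists 21 passed with the preset correlation and 9 with an estimated one. Of 281 called list members 23 lost their call or changed direction in at least 1 of 20 alternatives, including 7 of the 13 interferon genes. The stricter fold threshold was not among these alternatives. The counts of members adjusted over the list alone were equal to those given in 24 of the 25 lists. These groups differ in Xist and Y-linked transcripts as well.

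**Figure D3:**
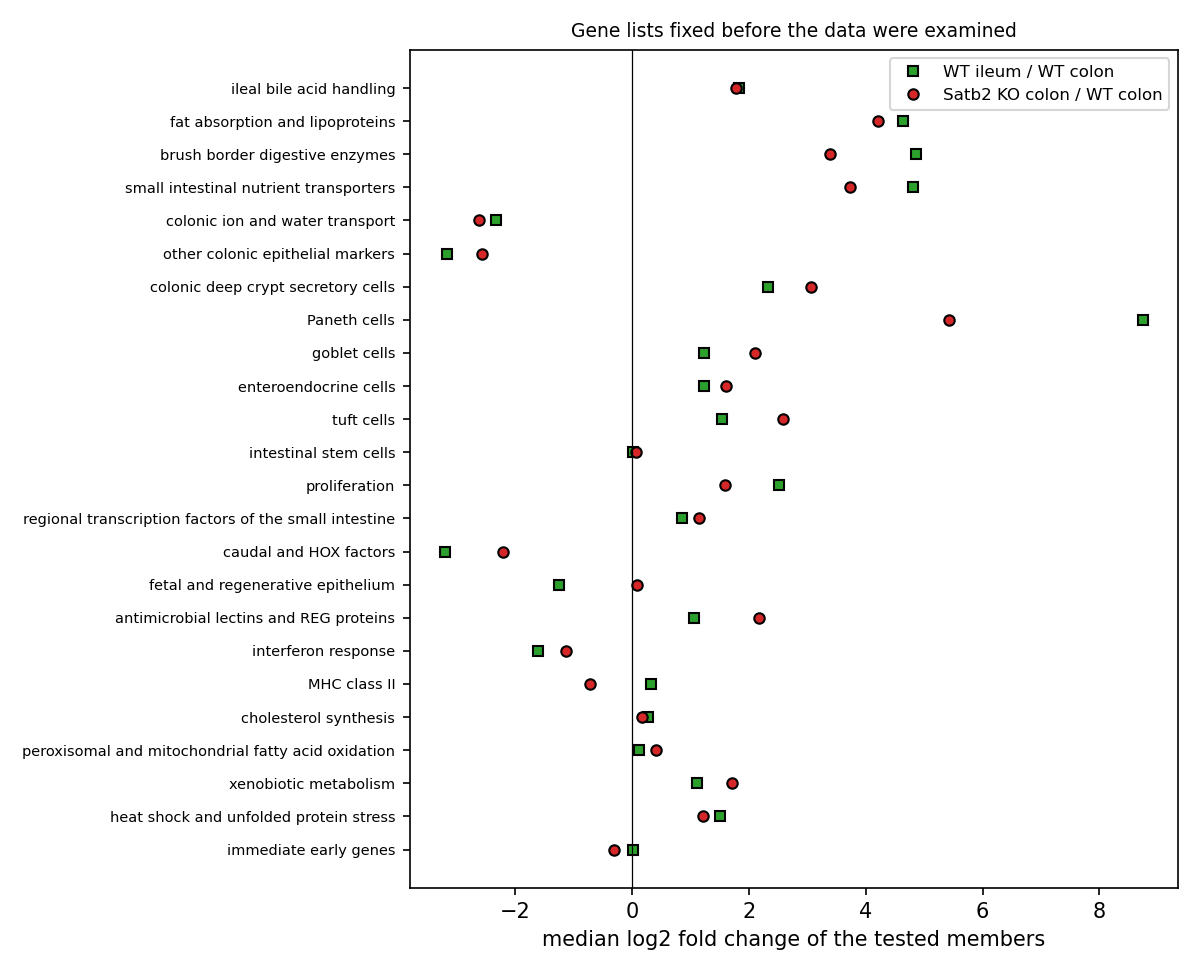
Median log2 fold change (horizontal axis) of the tested members of each gene list, against wild type colon, for wild type ileum (squares) and Satb2-deficient colon (circles), with genes at 0 counts placed at their bound. For fat absorption the medians are 4.64 and 4.21, and for colonic ion and water transport -2.33 and -2.63.

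How far the change followed the regional difference was asked with the 1680 genes higher and 1278 lower in wild type ileum by a log2 fold change of at least 1. Of the ileum-higher genes 1474 (87.7%) were higher in Satb2-deficient colon and 7 lower. Of the colon-higher genes 983 (76.9%) were lower and 24 higher. Both comparisons share the wild type colon libraries, and 3 libraries cannot be divided into separate controls of 2 each. In 20 simulations of an unchanged knockout the shares were 0% and 0.0037%. Such a knockout gave 0.45 called genes on average, so shares this low were set by the simulation. They do not show the share expected from a knockout with many changes unrelated to region. Independent lists would overlap in 494 and 335 genes. Part of the excess may come from the shared libraries. In the simulations they added 0.0717 to the mean product of the 2 log2 fold changes over region genes, against 8.07 observed. These values argue against the shared libraries as the main source of the excess.

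Across region genes the log2 fold changes correlated at 0.925 (simulated 0.0559). Their covariance, taken as the mean product, was 8.07 against 0.0717 that shared libraries add. The signs agreed in 96.6% of genes (simulated 54.4%). With the shared covariance taken off, Satb2-deficient colon lay at 0.812 of the distance from wild type colon to wild type ileum, a measure in which genes with large fold changes weigh most. The median fraction per gene was 0.787 for ileum-higher and 0.65 for colon-higher genes. Placed library by library on log2 CPM, Satb2-deficient colon was at 0.785 ± 0.00925, wild type colon at 0.0105 ± 0.0159 and wild type ileum at 0.992 ± 0.00552 (SD, n = 3). Of the ileum-higher genes 668 rose but stayed below ileum, 625 rose with no called difference from ileum, and 181 rose past it. Of the colon-higher genes 435 fell but stayed above ileum, 487 fell with no called difference from ileum, and 61 fell past it. A missed call does not show equal levels.

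**Figure D4:**
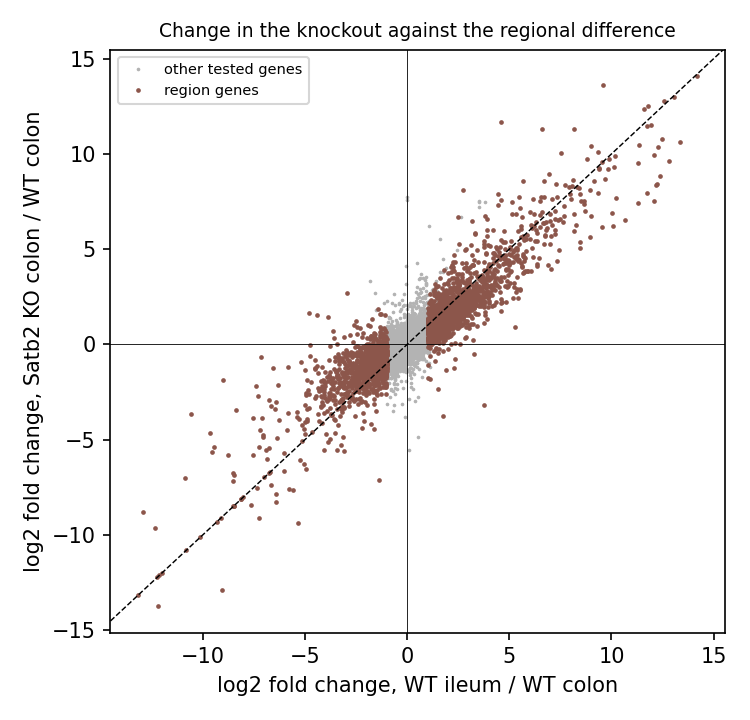
Each point is a tested gene, with the log2 fold change of wild type ileum over wild type colon on the horizontal axis and of Satb2-deficient over wild type colon on the vertical axis. Region genes are coloured, fitted values of genes without counts in a group depend on the prior count, and the dashed line marks equal change. The correlation over region genes is 0.925, and 668 ileum-higher and 435 colon-higher genes moved but stopped short of ileum.

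The comparison of Satb2-deficient colon with wild type ileum asked what still sets them apart. Some colonic transcripts stayed above ileum although they had fallen: the ketogenic enzyme Hmgcs2 was at 14.8 ± 0.234 CPM against 0.124 ± 0.135 in ileum and 191 ± 13.7 in wild type colon, and Ly6g at 63.3 ± 8.64 against 12 ± 1.91 and 378 ± 5.48. The forkhead factor Foxd2 (17.6 ± 0.908 against 0.481 ± 0.168 CPM) and the glycosyltransferase B3galt5 (17.4 ± 1.15 against 1.04 ± 0.368) did the same. Genes lower than in ileum included Fabp6 (-1.93 ± 0.12), Anpep (-2.56 ± 0.11), Gata5 (-2.69 ± 0.10) and the defensin Defa22 (-3.50 ± 0.14), as log2 fold changes with SE.

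Of 16 brush border enzymes 14 were lower than in ileum and none higher (camera adjusted p = 8.8e-16, and adjusted p = 0.103 with an estimated correlation). Of 15 Paneth genes 9 were lower and 2, Mmp7 and Ang4, higher (camera adjusted p = 8.1e-06, and adjusted p = 0.221 with an estimated correlation). Proliferation genes were lower in 19 of 20 cases, with Mki67 at 15.5 ± 2.77 against 48.3 ± 2.03 CPM (camera adjusted p = 3.1e-10, and adjusted p = 0.176 with an estimated correlation). Goblet genes were higher in 10 of 15 cases (camera adjusted p = 1.0e-07, and adjusted p = 0.103 with an estimated correlation), such as Agr2 (1.32 ± 0.08) and Klk1 (1.48 ± 0.09). Fetal and regenerative genes were higher in 8 of 9 cases, including Ly6a (339.6 ± 40.2 against 78.5 ± 7.79 CPM) and Clu (185 ± 20.6 against 87.5 ± 3.58 CPM), with a camera adjusted p of 1.7e-09 and adjusted p = 0.169 with an estimated correlation. In wild type ileum against wild type colon 7 of these 9 genes were lower and 2 higher (camera adjusted p = 0.00266, and adjusted p = 0.226 with an estimated correlation). The list did not pass between Satb2-deficient and wild type colon. Against ileum, fatty acid oxidation genes were higher in 12 of 18 cases, Hmgcs2 among them, and lower in 2 (camera adjusted p = 5.2e-06, and adjusted p = 0.172 with an estimated correlation). Nutrient transporters were lower in 10 and higher in 3 of 15 cases (camera adjusted p = 1.6e-04, and adjusted p = 0.172 with an estimated correlation). Genes of deep crypt secretory cells were higher in 5 and lower in 2 of 8 cases, of tuft cells higher in 4 and lower in 0 of 7, and of xenobiotic metabolism higher in 11 and lower in 4 of 20 (camera adjusted p = 0.00196, 0.0169 and 0.00753, and adjusted p = 0.172, 0.176 and 0.312 with an estimated correlation). Of 18 fat absorption genes 12 were lower and 4 higher, with a median log2 fold change of -0.49 and a mean of 0.07, which differ in sign (camera adjusted p = 0.0161, and adjusted p = 0.252 with an estimated correlation). In all 2463 genes were higher and 2473 lower than in ileum (edgeR quasi-likelihood, adjusted p under 0.05), and 677 and 476 of them by a log2 fold change of at least 1. Of 25 lists 11 passed camera with the preset correlation and 0 with an estimated one, and the counts adjusted over the list alone were equal in 17 lists.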

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

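The settings without X and Y genes, with a GC and length offset and with a prior count of 2 were chosen after the data were examined. The counts of called genes in the 3 comparisons were within 1.5 times the reported count under each alternative run except the planned fold threshold. With a log2 fold change of at least 1 the counts were 1544 higher and 929 lower in Satb2-deficient against wild type colon, 1680 and 1278 in ileum against colon, and 677 and 476 in Satb2-deficient colon against ileum, a stricter criterion by construction. The next values are, in order, the share of ileum-higher genes called higher, the share of colon-higher genes called lower, and the share of region genes in which Satb2-deficient colon differs from ileum (reported as 87.7%, 76.9% and 56.2%). They were 71.4%, 55.6% and 27.9% with the fold threshold, 83.3%, 71.3% and 49% with no filter, and 90.2%, 81.8% and 61.2% with 1 CPM in 3 libraries. They were 74.8%, 69.6% and 46.1% for region genes of any fold, and 95.2%, 84.7% and 62.7% for a log2 fold change of at least 2. On the deposited normalized signal the ileum-higher and differing shares were 84.5% and 50.4%, and with only the compared groups in the fit the colon-higher and differing shares were 79.9% and 61.3%. With each library left out the shares ranged over 83.3 to 88.2%, 71.6 to 78.4% and 48.3 to 56.2%, where fewer samples were fitted. The fraction of the distance was 0.788 with no filter, 0.787 on the normalized signal, 0.823 for a log2 fold change of at least 2, 0.791 with a prior count of 2, and 0.794 to 0.819 with each library left out, against 0.812. Apart from the settings whose construction gives the reason, the cause was not tested.

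Of list calls over the 3 comparisons, 52 passed with the preset correlation and 17 with an estimated one. With fry 62 passed, and 11 list results gained a call. The 1 that lost its call was fat absorption in Satb2-deficient colon against ileum (fry adjusted p = 0.086). With any 1 library left out, no list lost its call. Of 11517 values of named genes under the alternatives, 11216 stayed on the same side of the threshold, and the called ones among them kept their direction. Direction was not compared for values called in neither fit. A call was lost in 230, of which 105 with the stricter fold threshold, and gained in 69. Among values with a call, 2 changed sign, both with the GC and length offset. There Fabp2 went to -0.25 and Ldlr to 0.000703 (log2, Satb2-deficient against wild type colon). The cause was not tested. No scaling moved the median of all genes by 0.1 or more, but each scaling centres most genes, so a small shift was set by the methods. The replicate numbers did not pair the samples: same-numbered libraries of different groups deviated together with correlations of -0.0704 to 0.0664, and not every library correlated best with its own number. With the replicate block the counts were 3919 and 3516, 3988 and 3734, and 2450 and 2440 for the comparisons in the order above, the shares 87.4%, 76.8% and 55.2%, and the fraction 0.811. Depth limits genes near the floor, such as the posterior HOX genes in ileum, to bounds.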

Other observations

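The count of genes outside both wild type groups and the tests of a cell mixture, of tissue origin, of sex and of scaling were chosen after the result was seen. In Satb2-deficient colon 237 genes were higher and 79 lower than in both, each by a log2 fold change of at least 1 and an edgeR adjusted p under 0.05. The retinol-binding protein Rbp2 reached 594 ± 10.4 CPM against 57.2 ± 5.32 in wild type colon and 104 ± 3.53 in ileum (SD, n = 3). The fatty acid carriers Fabp1 (60.2 ± 14.9 against 0.201 ± 0.26 and 1.4 ± 0.7 CPM) and Cd36 (44.1 ± 4.04 against 0.0358 ± 0.062 and 7.73 ± 1.14 CPM) went the same way, as did the oxidoreductases Cyp2c29 (302 against 0.0179 and 18.8 CPM) and Adh4 (105 against 0.0358 and 12). The sulfotransferase gene Sult6b2 had no count in wild type colon and 21.6 ± 2.28 CPM in Satb2-deficient colon. Lower than in both were the ion and amino acid carriers Slc9a3 (15.4 against 384 and 33.4 CPM) and Slc6a14 (24.6 against 945 and 98.9), named after their values were seen, and the brush border enzymes Mep1a and Xpnpep2.

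The first pattern is that Satb2-deficient colon lies near wild type ileum, where a mixture of wild type ileum and colon cells would bring all colonic transcripts in 1 proportion, but over 23 genes abundant in colon and more than 10 times lower in ileum the implied share of colon cells had a median of 2.21% and was 39.9% at its highest, for Ubc, and 14% for Ly6g, against 0.594% for Car2, and 7 genes lay at or under the ileum level. These unequal shares argue against a mixture as the whole cause (the 90th percentile was 948 times the 10th, which is itself at the counting floor). An origin of the crypts in a more anterior segment cannot be told apart from an effect of Satb2 loss: 642 colon-higher genes were still above ileum in Satb2-deficient colon, but no Satb2-deficient group of another segment was analysed here. The sex of the animals cannot be told apart from the comparison either, because Y-linked transcripts were in every wild type colon library and in no other, and the 0.991 times frequency of X and Y genes among called against tested genes bounds only an effect of these chromosomes. The genotype itself stays among the open explanations.

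The second pattern is the set of genes outside both wild type groups. Factors in steps up to 3 (log2, either way) were put on all libraries of any 1 group. The total above and below both was never under 298 against 316, so no factor tried removed the set. TMM factors already centre the genes, so a lowest total near no added factor was likely beforehand, and a scaling error was not excluded. The split between directions did depend on the factor. With 0.25 on Satb2-deficient colon it was 172 higher and 154 lower, against 237 and 79. Errors in 2 groups at once were not tested. Linked segments of another strain would place such genes side by side. Of 312 genes 35.3% had another of a different name family within 1 Mb, against a 95th percentile of 42.3% in 1000 random sets. This argues against linkage for the set as a whole. A segment that holds only a few of these genes would not move the share, and genes near Satb2 were not counted apart, so such a segment was not tested. A candidate explanation was a more proximal small intestinal profile, tested on markers whose values had not been looked at, and it stayed open. Of 11 distal markers 10 were lower than in ileum and 1, Phgr1, higher (camera p = 1.4e-05, and p = 0.0442 with an estimated correlation), but the 26 proximal markers, 9 higher and 4 lower, did not pass (p = 0.229, median log2 fold change 0.14).

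For each comparison the 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. In fits of the 2 groups alone the real split gave 7362 genes for Satb2-deficient against wild type colon, 7698 for ileum against colon and 4709 for Satb2-deficient colon against ileum. In each comparison 1 of the 10 splits, the real one, gave as many. The highest of the other splits was 0 genes in all 3 comparisons with edgeR, and at an unadjusted p under 0.05 the highest were 152, 163 and 628.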
